A study of Oryza sativa with 8 samples.

How the data were processed

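Total RNA of rice seedlings was compared on 8 dual-channel Agilent 4x44K rice arrays, 4 on each of 2 slides. Per the labels, 2 arrays compare RH (Rathu Heenati, resistant) with 02428 (susceptible), 3 compare the resistant with the susceptible F2 pool (RB vs SB), all infested for 24 h, and 3 compare the resistant pool with and without insects (RB vs RN). Slide 1 held both RH vs 02428 arrays and RB vs SB arrays 1 and 2, and slide 2 held RB vs SB array 3 and the RB vs RN arrays. Cy5 marked the first-named sample on every array.

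Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.5.1.1 and give the mean foreground and median local background intensity of each spot in each channel, with no correction. Per the file headers, they also give processed signal intensity, corrected for background and spatial trend and normalized between dyes within the array, and a log10 ratio of the processed Cy5 over Cy3 signals. The deposited value table holds a log2 ratio per probe and array. How it was made is not given in the sources used here. Set against the scanner files, its columns are the log2 ratio of Cy3 over Cy5, opposite in sign to the comparisons' names, with slopes on the log10 ratio from -3.33 to -3.32 and r from -0.998 to -0.933 on 6 arrays. The columns of RB vs RN arrays 2 and 3 had r of -0.0044 and -0.0022 as listed, and of -0.957 and -0.978 when their values were put in the spot order of the array. They were used in that order, and only as an alternative.

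Each array had 45151 spots, 43734 of them for genes. Spots marked as outliers by the scanner software (221 to 319 per array) and control spots were left out. Mean foreground signals were corrected with limma's normexp method (offset 50) against the median background and normalized by loess within the array, with no scaling between arrays. The normexp fit was run without the outlier spots, because a few of them were judged to have corrupt background values that dominated the fit. This choice was made after seeing the data, and the fit with them kept is among the alternatives. Spots of 1 probe were averaged. Of 42477 probes, 41889 carried a locus ID. A gene was represented by its probe with the highest mean signal over all arrays, and had to be well above background in at least 1 channel on every array of at least 1 comparison. A channel is called near background where it was not well above it by the scanner software's test. Where that held on every array of a comparison, the fold is given as a bound, against the lowest signal called well above background on the array or the gene's own signal where that was higher. Precision is limited by the number of arrays, 2 or 3 per comparison.

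All 8 arrays were fitted in 1 linear model with 1 coefficient per comparison in limma 3.58.1 (lmFit and eBayes, two-sided, 8.56 total degrees of freedom) under R 4.3.3 with data.table (version 1.17.8); figures used matplotlib 3.10.9. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The fold minimum of 2 was planned as an alternative, and its counts were added as results after seeing that at least 71.0% of genes passed. Gene lists, 23 in number and matched to the array's descriptions or locus IDs, were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Overlaps of calls were compared with the number expected for independent lists and, where RB was shared, with 20 simulated draws with no effect. Chromosomes were taken from the locus IDs and tested with Fisher's exact test, two-sided, among genes past the test in RH vs 02428. The reference table at hand names an Os locus ID in 1 of 39387 rows and was not used for positions. Tested on simulated data with 200 changed genes among 25843, the model recovered 80.6% to 92.5% of changes of 0.25 on the log2 scale and at least 98.5% of changes of 0.5, with 6 to 17 false calls. The simulated noise held only the spread between these arrays, without dye bias or spread between RNA samples. Recovery and false calls therefore hold for that spread alone.

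The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, except where a choice is said to be made after. The tests that weigh explanations, and their bounds, were written after the counts, list results, correlations and chromosome shares had been seen, and before the values they test were computed, except where said. The rule named, per comparison, the 8 genes with the largest ratio each way among those past the test with the same sign on every array and an informative description. It added up to 3 members with the largest absolute ratio of each list past its test. For the contrast of RH vs 02428 with RB vs SB and for each overlap it named the 5 largest each way, and for each enriched chromosome the 3 genes with the largest smaller ratio.

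The alternatives were no background correction, the scanner software's processed signals, median centring, scaling between arrays, no filter or a strict filter on dim probes, the mean of a gene's probes, each comparison fitted alone, the slide as a fixed or random block, the replicate number as a block, the deposited value table, an adjusted p under 0.01, the fold minimum, an estimated correlation, windows in place of chromosomes, a background of all measured genes, and each array left out in turn. Added after seeing the data were the outlier spots kept in the background fit, the value table as listed, and each slide alone. Probes without a locus ID were left out of the comparisons.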

Results

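Gene expression was compared in rice seedlings (Oryza sativa) that differed in resistance to the brown planthopper (BPH), an insect that feeds on phloem sap. RH is the resistant cultivar Rathu Heenati and 02428 is a susceptible cultivar. RB and SB are pools of 10 highly resistant and 10 highly susceptible plants from the F2 of their cross, both infested for 24 h, and RN is the resistant pool without insects. The seedlings were 10 days old, and the infested ones received 10 nymphs each. Total RNA was hybridized to 8 dual-channel rice arrays, with 2 arrays for RH vs 02428, 3 for RB vs SB and 3 for RB vs RN. The first-named sample was always labelled with Cy5 and the second with Cy3, so a log2 ratio above 0 means more signal in the first-named sample. The deposited table of values has the opposite sign. No array had the dyes exchanged, so a gene-specific dye bias is not removed from any ratio. In each array 80.6% to 84.8% of gene spots were well above background in Cy5 and 85.5% to 86.7% in Cy3, and no spot was saturated. Of 29689 loci on the array, 25843 genes were tested. The array gives locus IDs, from which the chromosome and gene order are known, but no start, end or genome build is given in the sources used here.

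Log2 ratios of arrays of the same comparison correlated across genes with r of 0.996 for RH vs 02428, 0.951 to 0.964 for RB vs SB and 0.973 to 0.976 for RB vs RN. The median SD between arrays was 0.031, 0.048 and 0.040, below the SD of duplicate spots within an array, which was 0.086, 0.090 and 0.094. The labels call the arrays biological replicates, and no label says that plants were grown or pooled again for each. The p-values therefore measure only the spread between these arrays. With so little spread, 71.0% to 85.0% of genes passed the test in each comparison, and counts of genes that also differed at least 2-fold are given beside those counts.

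The comparison of RH with 02428 asks how infested seedlings of the resistant and the susceptible parent differ. Among genes with an informative description, the highest ratios were those of Os12g0199000, a beta-glucosidase aggregating factor, with a log2 ratio of 7.10 ± 0.066 (SD, n = 2), and Os10g0186800, a protein with a nucleic acid-binding OB-fold, with 6.52 ± 0.032. A chloroplast Clp protease subunit, Os12g0230100, was higher by 6.38 ± 0.032, and the transcription factor MADS56, Os10g0536100, by 6.10 ± 0.054. At the other end, the ankyrin repeat genes Os01g0942900 and Os01g0943800 had log2 ratios of -8.02 ± 0.015 and -7.85 ± 0.15. The callose synthase Os06g0112800, whose class of enzyme makes the wall polymer callose, had a log2 ratio of -7.55 ± 0.17. The P450 gene Os11g0465200 had -7.07 ± 0.031, on signals well above background in both channels of both arrays.

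Further described genes higher in RH were the acid phosphatase Os05g0191500 (6.25), the En/Spm-like transposon protein Os06g0271500 (5.93), the homeodomain-like Os06g0660600 (5.89) and Os11g0687100, with a von Willebrand factor type A domain (5.76). Further described genes lower in RH were the lysine decarboxylase-like Os03g0857900 (-7.69), the CBS domain gene Os04g0136700 (-7.31) and the aspartic peptidase Os06g0119600 (-7.24), whose Cy5 signal was near background on 1 array. Os10g0180800, with an EGF-like calcium-binding domain, was at least 131-fold lower in RH, because its Cy5 signal was near background on both arrays. Probes of a gene could differ: the 4 probes of Os03g0857900 ranged from -7.69 to 0.71, and the 3 probes of Os05g0191500 from 3.35 to 6.25. Of 7169 genes with several probes, 835 (11.6%) had probes more than 2-fold apart in RH vs 02428, against 51 in RB vs SB and 47 in RB vs RN. In ratios of RH vs 02428, weaker binding of a cultivar's alleles to the probes cannot be told apart from lower expression.

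Genes of phenylpropanoid synthesis, the route to lignin, flavonoids and many phenolic defence compounds, were shifted towards RH. Of 64 measured members, 39 were higher in RH, 15 were lower and 10 did not pass, and 54 passed when adjusted over the list alone. Their median log2 ratio was 0.19 and their mean 0.35, and limma's camera gave an adjusted p of 0.0142 over 23 lists with a preset correlation. The call was lost with an estimated correlation, at an adjusted p of 0.108, and over all alternatives the adjusted p ranged from 0.00746 to 0.108. At least 2-fold differences were seen for 18 members higher and 5 lower in RH. The members with the largest differences went both ways. The phenylalanine ammonia-lyase Os12g0520200, of the enzyme class that opens the pathway, had a log2 ratio of -6.54 ± 0.25. The caffeoyl-CoA O-methyltransferase Os06g0165800, of a class that acts in lignin synthesis, had 3.76 ± 0.10, and the chalcone synthase Os04g0116800, of the class that opens flavonoid synthesis, had -3.42 ± 0.066. No other list of the 23 passed in this comparison, but the number that passed depended on the processing: it was 6 with median centring, 3 with a strict filter on dim probes, 2 with ratios scaled between arrays and 2 with the slide as a fixed block.

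In limma, 21976 of 25843 genes passed an adjusted p of 0.05 in RH vs 02428, with 9927 higher and 12049 lower in RH. The majority turned with the signals used: 45.2% of the genes that passed were higher in RH, but 54.2% with the scanner software's processed signals and 54.2% with the deposited value table. Of these 21976 genes, 4662 differed at least 2-fold, 1652 higher and 3010 lower. The 16 genes with the largest ratios among those with an informative description had adjusted p of at most 3.87e-12. Among the 2-fold calls, 987 had 1 channel near background, and 802 of those were lower in RH with a dim Cy5 signal. When log ratios were scaled to the same spread on all arrays, 2271 genes differed at least 2-fold, and 24.2% of them were higher in RH, against 35.4% without scaling and 45.3% with the processed signals.

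The comparison of RB with SB asks how the resistant and the susceptible F2 pool differ after 24 h of infestation. Among genes with an informative description, those with the largest ratios above 0 were a pair of lipoxygenases, a family that oxidises fatty acids and includes enzymes of jasmonate synthesis. Os12g0559200 had a log2 ratio of 4.27 ± 0.041 (SD, n = 3) and Os12g0560200 of 3.48 ± 0.032. They were followed by the beta-glucosidase aggregating factor Os12g0247700, at 3.31 ± 0.0084, and the Bowman-Birk trypsin inhibitor Os01g0124000, at 2.82 ± 0.038, from a family that blocks digestive proteases. The O-methyltransferase Os04g0196200 had 2.68, the ribonucleases Os09g0537700 and Os09g0538000 had 2.46 and 2.26, and the transferase Os12g0458100 had 2.37.

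Of the 8 genes with an informative description and the largest ratios below 0, 7 lay on chromosome 4. The protein kinases Os04g0307500 and Os04g0370900 had log2 ratios of -3.68 ± 0.072 and -3.51 ± 0.038. The F-box gene Os04g0194000 was at least 9.74-fold lower in RB. Another F-box gene, Os04g0191600, had -3.55 ± 0.10, with Cy5 near background on 2 arrays and 4 probes that ranged from -4.61 to -0.36. The glycosyltransferase Os04g0206700 had -3.27, Os04g0319600, with a motif that binds S-adenosylmethionine, had -3.25, and the exonuclease-domain gene Os04g0225100 had -3.22. The gene off chromosome 4 was the glycoside hydrolase Os05g0542900, at least 10.3-fold lower in RB.

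Of 23 lists, 4 were shifted towards RB with the preset correlation and 1 with an estimated correlation. With median centring 9 lists passed. Among 302 measured genes for ribosomal proteins of the cytosol and organelles, 213 were higher in RB, 22 were lower and 67 did not pass, and 237 passed when adjusted over the list alone. The shift was small, with a median log2 ratio of 0.16 and 1 member that differed 2-fold (camera in limma, adjusted p = 3.69e-11, and adjusted p = 0.0547 with an estimated correlation, the highest over all alternatives). The member with the largest difference, Os04g0247700, was lower in RB at -1.83 ± 0.066, and is named by a domain like that of ribosomal protein L9. The plastid protein L18, Os03g0828100, was higher at 0.96 ± 0.070, and the plastid-specific protein Os03g0856500 at 0.60 ± 0.29.

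Among 99 photosynthesis genes, 66 were higher in RB, 17 were lower and 16 did not pass, and 83 passed when adjusted over the list alone. Their median log2 ratio was 0.20, 8 members were at least 2-fold higher and 1 lower, and the list passed camera in limma at an adjusted p of 1.74e-06 with the preset correlation. It was the one list that also passed with an estimated correlation, at an adjusted p of 0.0167, the highest over all alternatives. Genes annotated as the small and the large subunit of Rubisco, the enzyme that fixes carbon dioxide, were higher. They were Os12g0274700, annotated as the small subunit, at 1.47 ± 0.021, and Os06g0598500, annotated as the large subunit, at 1.38 ± 0.060. What RNA the probe of Os06g0598500 binds was not tested. The photosystem II protein Os01g0773700 had 1.38 ± 0.070 on its brightest probe, and its 3 probes ranged from 0.03 to 1.38. Each of these genes was also above 0 in RH vs 02428 and RB vs RN. Os12g0274700 had 0.62 and 1.22 there, Os06g0598500 1.40 and 1.68, and Os01g0773700 1.31 and 1.34. The list's medians there were 0.19 and 0.13, and it passed in neither. With Cy5 on the first-named sample throughout, a dye bias of these genes cannot be told apart from a difference between the pools.

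Among 42 genes of terpenoid synthesis, 25 were higher in RB, 10 were lower and 7 did not pass, with a median of 0.19 and 35 members past the test when adjusted over the list alone. Camera in limma gave this list an adjusted p of 0.00884, an adjusted p of 0.0547 with an estimated correlation, and an adjusted p of 0.129 when spots marked as outliers were kept in the background fit, an alternative chosen after seeing the data. Over all alternatives it ranged from 0.00325 to 0.129. The terpene synthases Os12g0491800 and Os03g0348200 had ratios of 1.45 ± 0.10 and 1.44 ± 0.10, and Os04g0340300 had -3.05 ± 0.029. Among 41 jasmonate genes, 22 were higher in RB, 9 were lower and 10 did not pass, with a median of 0.12 and 31 past the test when adjusted over the list alone. This list had an adjusted p of 0.0207 in limma's camera and an adjusted p of 0.0704 with an estimated correlation, the highest over all alternatives, of which the lowest was 1.28e-06. Its call was also lost with the scanner software's processed signals (adjusted p = 0.0684) and with the deposited value table (adjusted p = 0.061). Besides the lipoxygenases with the largest ratios, the other named member was the chloroplast lipoxygenase Os08g0508800, at -0.74 ± 0.029. That gene was also below 0 in RH vs 02428 (-0.87) and RB vs RN (-0.56), so a dye bias cannot be told apart there either.

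In limma, 18341 of 25843 genes passed in RB vs SB, with 8378 higher and 9963 lower in RB, and 508 differed at least 2-fold, 188 higher and 320 lower. The 16 described genes with the largest ratios had adjusted p of at most 2.46e-08. The 2-fold count depended on how signals were made: it was 953 with the processed signals, 955 with the deposited value table, 1043 with ratios scaled between arrays, 334 with a strict filter on dim probes and 331 with outlier spots kept in the background fit, the last chosen after seeing the data. Arrays 1 and 2 lay on 1 slide and array 3 on another: 16920 genes passed on slide 1 alone and 13498 on slide 2 alone, both run after seeing the data, and 18223 with the slide as a fixed term.

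The comparison of RB with RN asks how the resistant pool responded to 24 h of infestation. Among genes with an informative description, the highest ratios were those of the P450 gene Os10g0515900, at 3.51 ± 0.37 (SD, n = 3), the protein kinase Os06g0581500, at 2.62 ± 0.028, and the DnaJ co-chaperone Os04g0675400, at 2.50 ± 0.0043. The P450 genes Os11g0635500 and Os10g0320100, the latter a flavonoid 3'-hydroxylase, rose by 2.42 and 2.40. The Myb gene Os05g0488600 rose by 2.36, Os11g0687100 by 2.35 and the CONSTANS-type zinc finger gene Os06g0298200 by 2.35. Os11g0687100 was also among the 8 highest of the described genes in RH vs 02428.

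Among the genes that fell, Os02g0703600, a P450 gene that the array's description names P450 90C1, had -3.81 ± 0.072. The DRE-binding protein 1A gene Os09g0522200, of a class of transcription factors of the cold response, had -3.41 ± 0.072, and its 5 probes ranged from -3.54 to -2.79. The dicarboxylate cotransporter-like Os09g0484900 had -3.35, the NAM-domain gene Os01g0862800 had -2.99 and the RING-finger gene Os02g0759400 had -2.87. The universal stress protein Os10g0437500 had -2.75, Os04g0581100, of the isopenicillin N synthase family, had -2.74, and the thionin Os06g0514100, of a class of small antimicrobial peptides, had -2.74 ± 0.055.

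Of 23 lists, 2 rose with infestation with the preset correlation and 0 with an estimated correlation. With median centring 4 lists passed, and 4 with the slide as a random block. Among 42 genes of terpenoid synthesis, 28 rose, 8 fell and 6 did not pass, with a median of 0.31, 8 members at least 2-fold higher and none 2-fold lower, and 36 passed when adjusted over the list alone. They included the terpene synthase Os08g0168000, at 1.90 ± 0.045, and Os04g0180400, annotated as CYP99A1, a P450 whose family acts in the synthesis of momilactones, which are antimicrobial diterpenoids of rice, at 1.78 ± 0.019. The P450 gene Os02g0569900 had 1.75 ± 0.046. Camera in limma gave this list an adjusted p of 0.000706, and an adjusted p of 0.0825 with an estimated correlation. Over all alternatives it ranged from 4.56e-06 to 0.637, the latter with the deposited value table as listed. Among 302 ribosomal protein genes, 225 rose, 32 fell and 45 did not pass, with a median of 0.19 and no 2-fold change, and 258 passed when adjusted over the list alone. That list had an adjusted p of 1.31e-10 in limma's camera and an adjusted p of 0.0825 with an estimated correlation, and over all alternatives it ranged from 1.32e-23 to 0.26, the latter with that table as listed. Its members with the largest changes were those for L30 (Os01g0812800, 0.74 ± 0.049), L19 (Os03g0337800, 0.65 ± 0.054, with 4 probes from 0.18 to 0.65) and L41 (Os03g0781500, 0.63 ± 0.071).

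In limma, 19589 of 25843 genes passed in RB vs RN, with 9278 higher and 10311 lower after infestation, and 882 changed at least 2-fold, 281 higher and 601 lower. The majority turned here too: 47.4% of the genes that passed were higher, but 52.9% with the processed signals and 53% with the deposited value table, and at 2-fold the share higher went from 31.9% to 40% with either. The 16 described genes with the largest changes had adjusted p of at most 6.07e-09. All 3 arrays lay on slide 2, so no value from another slide exists for this comparison. The deposited value table gives another result if read as listed: 7138 genes passed and 375 of them changed at least 2-fold, because the values of 2 of its columns stand in another order than its probe names.

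**Figure D1:**
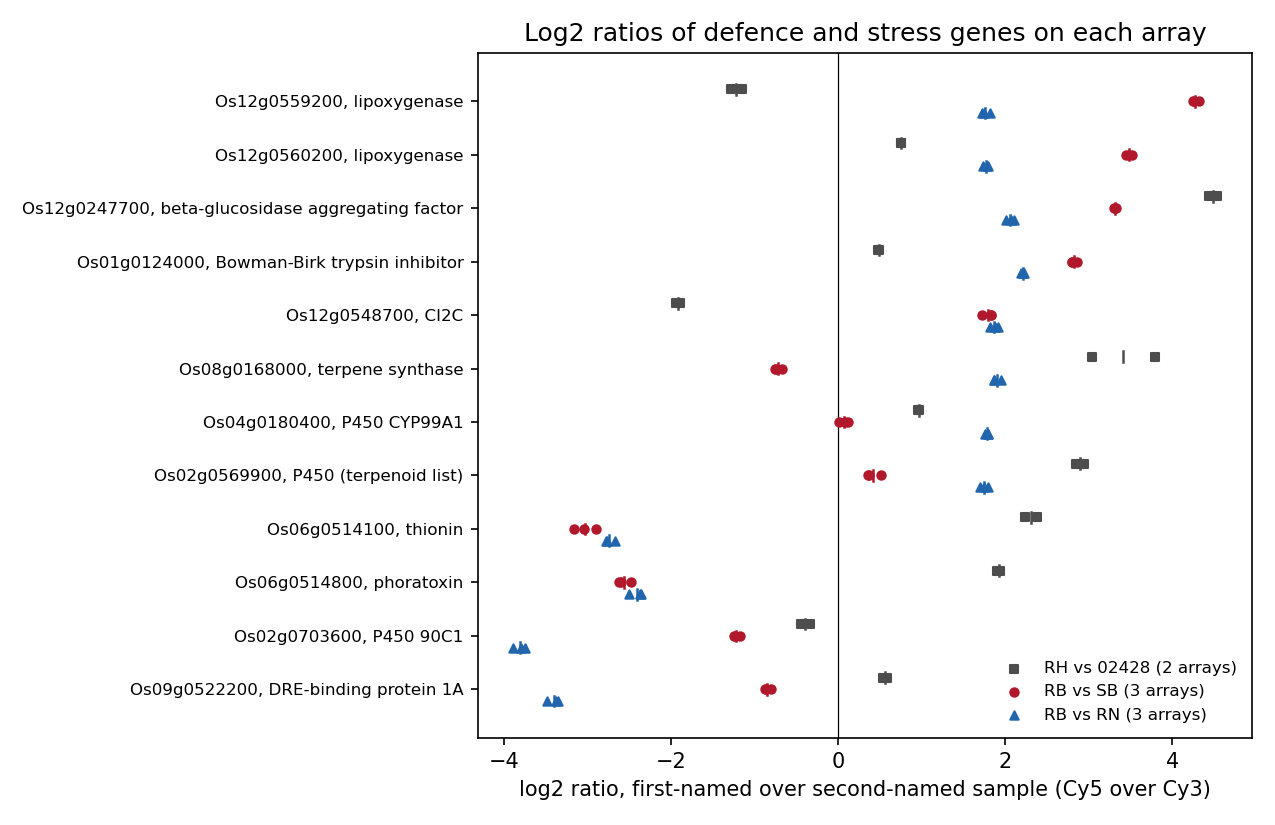
Log2 ratios (first-named over second-named sample, x axis) of 12 of the named genes (y axis), picked after their values were seen, with 1 point per array, vertical ticks at the mean, and shapes for the 3 comparisons. The lipoxygenase Os12g0559200 was higher in RB than in SB (4.27) and RN (1.76) but lower in RH than in 02428 (-1.22), and the Cy5 signal of phoratoxin was near background in both pool comparisons, so that its ratios there are bounds.

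Genes that passed both pool comparisons show what distinguished the infested resistant pool from both the susceptible pool and its own uninfested state. By the smaller of their 2 ratios, the highest in both were the Bowman-Birk inhibitor Os01g0124000 (2.82 against SB, 2.21 against RN), the aggregating factor Os12g0247700 (3.31 and 2.06), CI2C (Os12g0548700, 1.80 and 1.87) and the lipoxygenases Os12g0560200 (3.48 and 1.77) and Os12g0559200 (4.27 and 1.76). The lowest in both were the thionin Os06g0514100 (-3.03 and -2.74), Os04g0581100 (-1.93 and -2.74), Os09g0246500, a conserved hypothetical protein (-1.62 and -2.06), and Os06g0514800, annotated as phoratoxin, a thionin-type peptide (at least 5.87-fold and at least 5.19-fold lower). The leucine-rich repeat gene Os01g0162300 was at least 6.94-fold lower than in SB and had -1.85 against RN, with Cy5 near background on 1 array there. RH vs 02428, with the same dye orientation, had the same sign for Os12g0247700 (4.49), Os12g0560200 (0.75), Os01g0124000 (0.48), Os09g0246500 (-2.21) and Os04g0581100 (-0.40). It had the opposite sign for CI2C (-1.91), Os12g0559200 (-1.22), the thionin (2.31), phoratoxin (1.92) and Os01g0162300 (0.14). Where all 3 ratios are alike, as for Os09g0246500, a dye bias cannot be told apart from a difference in RB. At 2-fold in both pool comparisons, 113 genes went the same way, 62 higher and 51 lower, against 2.04 and 7.44 for independent lists, and 8 went opposite ways. Without a fold minimum, 11755 genes went the same way (5310 higher and 6445 lower, against 3008 and 3975 for independent lists) and 3157 went opposite ways. RB was in Cy5 in both comparisons and may be the same RNA. In 20 simulated draws with no effect and shared RB values, the correlation across genes was 0.495 on average. The observed correlation, 0.420, lay below that value. The observed covariance was 0.0589 and the simulated one 0.000624, but the draws held only the spread between these arrays and not that between RNA samples, so they do not size the part due to the shared RB. That 0 genes passed both in the draws follows from the adjusted p when nothing differs. With 3 arrays the RB samples could not be split so that each part kept 2, so part of the excess of the overlap over independent lists may come from the shared RB.

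Differences between the pools could also be set against those between their parents. By the smaller of the 2 ratios, the highest in both were Os12g0247700 (4.49 for RH against 02428, 3.31 for RB against SB), the O-methyltransferase Os04g0196200 (5.13 and 2.68), the ADP-glucose pyrophosphatase Os04g0288100 (2.12 and 2.15), the P450 gene Os09g0275400 (2.75 and 1.83) and the amidase Os04g0184100 (at least 26.5-fold and 1.80). The lowest in both lay on chromosome 4. They were the kinases Os04g0307500 (-3.96 and -3.68) and Os04g0370900 (at least 51.9-fold lower in RH, -3.51 in RB), the F-box genes Os04g0194000 (at least 11.1-fold and at least 9.74-fold lower) and Os04g0191600 (at least 14.3-fold lower in RH, -3.55 in RB), and Os04g0297800, a conserved hypothetical protein (-6.81 and -3.43). In RB vs RN, with the same dye orientation, Os12g0247700 had 2.06, Os04g0288100 1.49, Os09g0275400 1.04, Os04g0196200 0.50 and Os04g0184100 -0.05. Those lowest in both had -0.53 to 0.56 there. Where a gene was high in all comparisons, as Os04g0288100 was, a dye bias cannot be told apart from a difference in expression. At 2-fold in both RH vs 02428 and RB vs SB, 268 genes went the same way, 67 higher and 201 lower, against 12.02 and 37.3 for independent lists, and 94 went opposite ways. Without a fold minimum 10311 went the same way (4395 higher and 5916 lower, against 3218 and 4645) and 5811 opposite ways. Across genes, which are not independent replicates, the log2 ratios correlated with a Pearson r of 0.196 and a Spearman rho of 0.240. RH vs 02428 with RB vs RN, which share dyes but by the labels no RNA, gave 0.160 and 0.236. For that pair, 230 genes went the same way at 2-fold and 70 opposite ways. Of the 230, 76 were higher and 154 lower, against 17.96 and 70 for independent lists. Without a fold minimum 10781 went the same way and 6291 opposite ways. An overlap above that of independent lists therefore does not by itself show that the pools follow the parents. Within slide 1, the one slide with RH arrays, r of RH vs 02428 with RB vs SB was 0.194, a value computed after seeing the data.

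Genes that differed the same way between parents and between pools were not spread evenly over the chromosomes. Chromosome 4 held the largest share: of genes past the test in RH vs 02428, 58.0% also passed the same way in RB vs SB there, against 45.8% elsewhere (Fisher's exact test, two-sided, adjusted p = 1.72e-23 over 12 chromosomes, on limma calls). Chromosomes 1 (53.5% against 45.8%, adjusted p = 7.03e-15) and 9 (57.7% against 46.3%, adjusted p = 4.78e-14) also held more than the rest in this exact test. With a 2-fold minimum in both, chromosome 4 held 108 of 396 genes (27.3% against 3.75% elsewhere) and chromosome 9 held 34 of 301 (11.3% against 5.37%), while chromosome 1 did not stand out (5.62% against 5.77%). Without that minimum, 4 chromosomes passed with the processed signals and 4 with median centring, against 3 here. Of the 125 genes on chromosome 4 that differed 2-fold between the pools, 108 were lower in RB. For chromosome 9 the named genes were Os09g0275400, the expansin-related Os09g0472900 (3.42 in RH vs 02428, 1.74 in RB vs SB) and the unannotated Os09g0570700 (at least 10.0-fold lower in RH, -2.25 in RB). For chromosome 1 they were the hypothetical Os01g0392600 (-4.74, with Cy5 near background on 1 array, and -2.63), the unannotated Os01g0855800 (-4.34 and -2.41) and the dehydrogenase Os01g0931000 (at least 3.03-fold and at least 3.04-fold lower). Genes in a linked region are not independent, so these p-values overstate the evidence.

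Along chromosome 4 the pool differences followed the parental ones most closely in 1 stretch. These slopes were added after the share on chromosome 4 had been seen. In windows of 100 measured genes in locus order, RB vs SB ratios were regressed on RH vs 02428 ratios over the genes that differed 2-fold between the parents. From Os04g0129500 to Os04g0384800, 5 successive windows had slopes of 0.36, 0.54, 0.50, 0.50 and 0.52, with SE of 0.034 to 0.059. In the same windows the slopes of RB vs RN ran from -0.05 to 0.06. The other windows of chromosome 4 with at least 10 such genes had RB vs SB slopes from -0.03 to 0.23. On the other chromosomes the RB vs SB slopes ran from -0.26 to 0.36, with a median of 0.04.

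**Figure D2:**
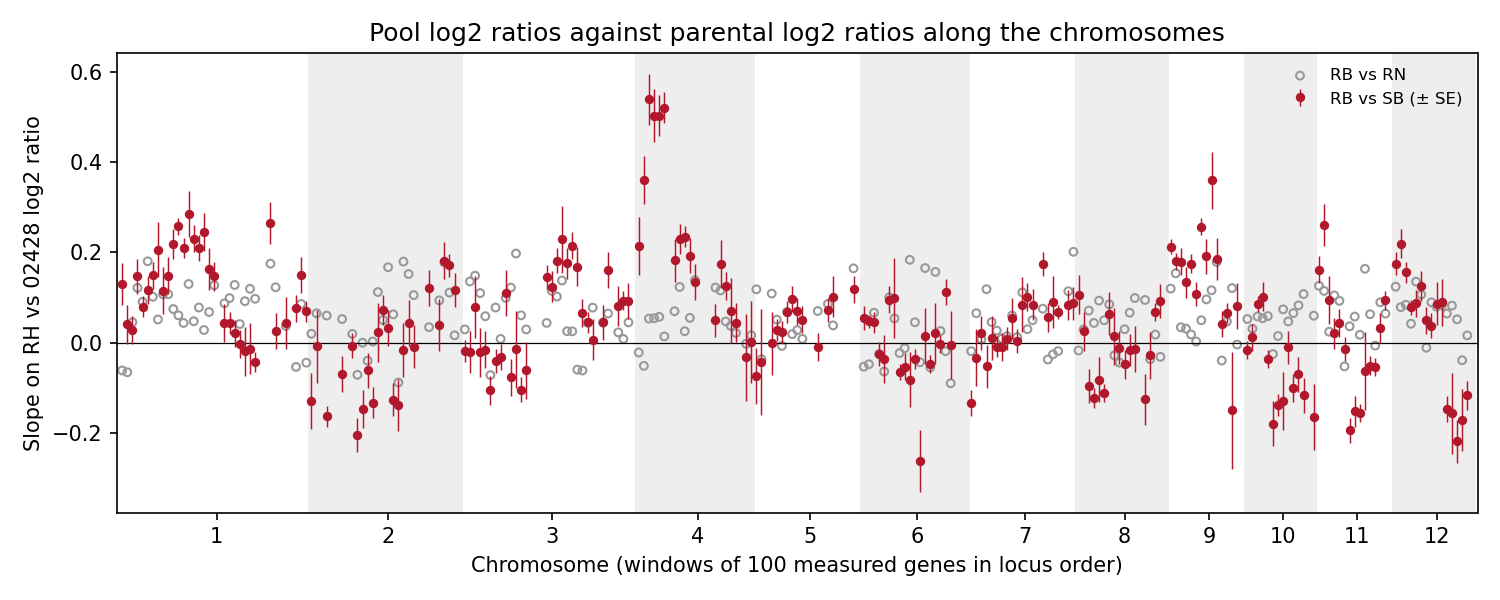
Slope of the pool log2 ratios on the RH vs 02428 log2 ratios (y axis, no unit) in windows of 100 measured genes along the 12 chromosomes (x axis), over genes that differed at least 2-fold between the parents; windows with under 10 such genes are left out. Filled points are RB vs SB with their SE and open points are RB vs RN; 4 neighbouring windows of chromosome 4 have RB vs SB slopes from 0.50 to 0.54.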

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

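The tests of weaker hybridization of RH alleles and of dye bias in the ribosomal protein probes were chosen after the results they bear on were seen, as were the 2-fold counts of microRNA-named probes; the other tests and their bounds were written after the patterns themselves had been seen but before the tested values were computed.

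The difference between resistant and susceptible seedlings was not the same in the parents and in the pools: in limma's contrast of RH vs 02428 with RB vs SB, 20650 of 25843 genes passed, and 4428 of them differed at least 2-fold. The 5 largest differences above 0 were those of the aggregating factor Os12g0199000 (7.64 on the log2 scale), the hypothetical Os10g0569800 (7.29), MADS56 (Os10g0536100, 7.08), the conserved hypothetical Os02g0216300 (6.92) and the phosphatidylinositol 3-kinase Os08g0307400 (6.82). The 5 largest below 0 were those of the hypothetical Os11g0475500 (-8.63), the conserved hypothetical Os08g0185300 (-8.56), Os08g0182400 (-8.51) and Os02g0163400 (-8.24), and the P450 gene Os11g0465200 (-8.53). All 10 had both channels well above background on the arrays that measured them. A dye bias shared by all arrays cancels in this contrast. RH vs 02428 alone had 4662 genes at 2-fold. Plants of an F2 carry alleles of both parents, so most parental differences would shrink between the pools whatever resistance does. The number of genes that passed therefore cannot tell whether resistance acts differently in parents and pools.

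Signal was also present in probes that no comparison used: of 510 probes named for microRNAs, 166 were well above background in both channels on all 8 arrays, against 0 of 153 negative control spots. Of these 166, limma's test passed 72.3% in RH vs 02428 and 63.3% in each pool comparison, and 12, 1 and 8 (for RH vs 02428, RB vs SB and RB vs RN) differed at least 2-fold. What RNA these probes bind was not tested.

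Genes that differed the same way between the parents and between the pools clustered on chromosome 4, where 108 did so at 2-fold. A gene-specific dye bias would recur in RB vs RN, where their median, turned to the direction of RB vs SB, was 0.052 (interquartile range 0.44) against a median size of 1.65 in RB vs SB. That narrowly missed the bound written before that value for excluding dye bias, which was to lie below 0.41 by more than the interquartile range, but it lay by more than that range below the 0.82 that the bias was said to need, a reading applied after the value was seen. Weaker binding of RH alleles to the probes cannot be told apart from lower expression by these arrays, since 88.0% of the genes were lower in RH and RB (95 of 108, exact 95% interval 80.3% to 93.4%), although the other 13 were higher. Over all chromosomes, chromosome 4 included, 201 of the 268 genes that went the same way at 2-fold were lower. In RH vs 02428 alone, 3010 of 4662 genes at 2-fold were lower in RH. Different shares of RH alleles in the 2 pools remain a candidate explanation: the highest window slope was 0.54 ± 0.057 (SE), close to the bound of 0.5, which was written after the clustering and before the slopes were seen, and such shares may come from the selection for resistance or from the small number of plants per pool.

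Log ratios of RH vs 02428 and RB vs RN correlated across genes (r = 0.160) although the labels give them no common RNA. A bias of single probes would not carry over to another probe of the gene. In 7081 genes with several probes, the correlation between probes was corrected for how well probes of a gene agree. It was 0.902 of that on the same probe (95% bootstrap interval 0.827 to 0.961, over 1000 resamples). The same-probe value was not corrected, so this share is overstated. Uncorrected, the correlation was 0.107 between probes and 0.141 on the same probe. A bias of single probes therefore does not account for all of the correlation, but may account for part of it. Expression tied to resistance that also responds to infestation predicts a correlation that carries over between probes and stays open as a hypothesis. A dye bias of the whole transcript, alike for all its probes, would pass this test too and may contribute, since no array had the dyes exchanged.

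Ribosomal protein genes were higher in RB in both pool comparisons, which may share the same RB RNA; with an estimated correlation neither call held (adjusted p = 0.0547 and 0.0825, camera in limma). A bias of bright probes would also move other genes of the same signal, but the list's medians of 0.16 and 0.19 lay above the highest medians of 10000 random sets matched on signal (0.01 and 0.06), by at least 0.13. A dye bias of these probes would also raise them in RH vs 02428, where their median was -0.0216, within the central 95% of the matched sets' medians, -0.12 to -0.01. Loess had already centred ratios along the signal, so the matched sets could show only a bias of bright probes left after it. They showed none of that size. Random sets also lack the correlation within the list, and the calls were lost once it was estimated. The value in RH vs 02428 argues against a dye bias only if no difference between the cultivars offset it. A difference in the RB seedlings, which no further data here could test, may remain as a hypothesis.

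For the pool comparisons, the signs of the 3 arrays can be set in 4 ways, too few for a share under 0.05. Arrays of a comparison agreed closely (r of at least 0.951 in RB vs SB and 0.973 in RB vs RN), so turning 1 of them had to cut the gene counts. Low counts in the other patterns therefore reflect the repeatability of arrays and cannot tell how plants or pools vary. For RB vs SB, the real signs gave 18341 genes, 508 genes at 2-fold and 4 lists, and the highest other sign pattern gave 2, 1 and 2. For RB vs RN, they gave 19589 genes, 882 at 2-fold and 2 lists, and the highest other gave 1, 1 and 2. In the lists of RB vs RN, 3 of the 4 patterns gave as many, and in each of the other counts 1 of 4, the real one.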

How the results depend on the processing

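Chosen after seeing the data were the outlier spots kept in the background fit, the value table as listed, each slide alone, and the use of the planned 2-fold counts as results of their own. Of the 115 values of named genes, all kept their direction and passed the test in every alternative fixed before the data were examined that was run on them; the strict filter measured 88, and the fold minimum was not run on single genes. The causes of the changes below were not tested unless one is given.

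With the processed signals the correlation of RH vs 02428 with RB vs SB was 0.175 (0.196 in the results) and RB vs SB had 953 genes at 2-fold, while the value table gave 0.174 and 955; the processed signals moved the median log2 ratio of all genes in RH vs 02428 from -0.05 to 0.05. Median centring gave 6, 9 and 4 lists (1, 4 and 2 in the results, for RH vs 02428, RB vs SB and RB vs RN) and a correlation of 0.234. Scaling between arrays gave RH vs 02428 2 lists and 2271 genes at 2-fold (24.2% higher, against 35.4%), and RB vs SB 1043. The strict filter gave RH vs 02428 3 lists, a correlation of 0.214 and 334 genes at 2-fold in RB vs SB. The slide as a fixed block gave RH vs 02428 2 lists, and as a random block RB vs RN 4 lists (with cameraPR, correlation within slides 0.101). By construction, an adjusted p under 0.01 left 0 lists in RH vs 02428, where phenylpropanoid synthesis had 0.0142, and the fold minimum left 4662, 508 and 882 genes, 4428 in the contrast of parents and pools, and overlaps of 268 and 113. An estimated correlation left 0, 1 and 0 lists. Windows in place of chromosomes gave 29 enriched windows, which lay on chromosomes 1, 3, 4, 9 and 12. The smallest p was that of a window on chromosome 11 with a lower share than elsewhere (15.6% against 47%, Fisher's exact test, adjusted p = 1.16e-07).

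Outlier spots kept in the background fit gave a correlation of 0.201 and 331 genes at 2-fold in RB vs SB, all among the 508, and ended the terpenoid call there (adjusted p = 0.129, with a range of 0.00325 to 0.129 over its alternatives; limma). The value table as listed, whose order breaks 2 arrays of RB vs RN, gave 6699 genes in RB vs SB (883 at 2-fold), 7138 in RB vs RN (375 at 2-fold), 12302 in the contrast, 0 lists in RB vs RN, a correlation of 0.174 and overlaps of 3555 and 1948; Os03g0337800 turned to -0.36 there, and 29 other named values no longer passed. On slide 1 alone the correlation was 0.194.

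Leaving out each array in turn gave 20372 to 20411 genes in RH vs 02428, 16605 to 17288 in RB vs SB and 18061 to 18245 in RB vs RN; the lone RH vs 02428 array is then assumed to vary like the others. The correlation ranged from 0.194 to 0.196. The same replicate numbers did not deviate together (correlations -0.0034 and -0.0037 for RH vs 02428 with RB vs SB, -0.0792, -0.0223 and -0.142 for RB vs SB with RB vs RN). Deviations from the mean of so few arrays are tied to each other, and arrays differed less than duplicate spots. These values therefore cannot tell whether the numbers pair the samples. The replicate block gave 21519, 17926 and 19274 genes and 4663, 508 and 882 at 2-fold, and 1, 5 and 2 lists, and changed no call of the lists named in the results. Signal limits the dim end: 987, 58 and 22 of the 2-fold calls had 1 channel near background.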

Other observations

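The tests of gene lists reported in this part were planned before the data were examined, while their 2-fold counts were chosen after.

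Of 153 measured genes for heat shock proteins, 40 rose and 83 fell in RB vs RN, 2 at least 2-fold up and 11 at least 2-fold down, with a median log2 ratio of -0.12 (camera in limma, adjusted p = 0.0818). Of 41 jasmonate genes, 10 rose and 24 fell in RB vs RN, with a median of -0.20 and an adjusted p of 0.107 in limma's camera. Of 211 cytochromes P450, 12 rose and 5 fell at least 2-fold in RB vs RN, and the list did not pass (adjusted p = 0.349 in limma's camera).

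Among 191 resistance proteins of the NBS-LRR type, a class of receptors that recognise pathogens and pests, 58 were higher and 114 lower in RH than in 02428, with 24 and 52 at least 2-fold and a median of -0.28 (adjusted p = 0.0905 in limma's camera). All 7 measured callose synthases were lower in RH than in 02428, with a median of -0.40, and as a list did not pass (adjusted p = 0.0661 in limma's camera). Weaker binding of RH alleles to the probes cannot be told apart from lower expression in either list. Among 70 WRKY transcription factors, 14 were at least 2-fold higher and 6 lower in RH, with a list adjusted p of 0.0543 in limma's camera. Markers of other tissue did not pass: the root markers had adjusted p of 0.973, 0.618 and 0.706 in limma's camera for RH vs 02428, RB vs SB and RB vs RN, and the seed-remnant markers had 0.727, 0.443 and 0.308.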
